A study of Mus musculus with 16 samples.

How the data were processed

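The series holds total RNA from 8 mouse ESC lines grown with LIF and after 12 days without it, 16 samples in all, hybridized to 16 Affymetrix arrays after labelling with a whole-transcript kit. The deposited values are log2 signals that the authors made with RMA in the affy package, per the submitters' processing notes; the versions of both and the probe set definition are not given in the sources used here. The values run from 0.98 to 14.21. Array medians were 4.72 to 4.85, and the correlation between pairs of arrays was 0.971 to 0.995. Signal over background sets what can be measured: probe sets near the floor carry little information on change.

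Of 65770 probe sets, 27 had no value on any array and were left out. A single gene symbol was given for 30439 probe sets, several for 2146 and none for 33185; only those with a single symbol were used. Symbols were brought up to date by Entrez identifier with a reference table of assembly GRCm38.p6 (22653 probe sets matched, 827 symbols updated), which served only for names, chromosomes and the order of genes. Where a gene had several probe sets, the one with the highest mean signal was kept, which gave 30102 genes. Genes were tested where the signal lay above the 40th percentile of the array on at least 3 arrays (22872 genes).

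Lines were classed from the labels as retaining a coiled coil (EBRTcH3, MBD3a, MBD3b, MBD3c, MBD-deleted) or lacking it (empty vector, coiled-coil-deleted, doubly deleted). The 2 arrays of a line share the cell line, a pairing that comes from the labels, and the fits of the response to LIF withdrawal held the line as a block. Models were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all tested genes of a comparison; a gene passed at an adjusted p under 0.05. There were 10 comparisons: LIF withdrawal over all lines, in the retaining lines and in the lacking lines; the difference of the last 2 (lacking minus retaining); lacking minus retaining lines with LIF and without; and the effects of deleting the MBD and the coiled coil across the 4 MBD3a constructs (MBD3a, MBD-deleted, coiled-coil-deleted, doubly deleted), in each condition, in an additive model. The deletion comparisons come from a single fit of both conditions, without a block by line. Adjusted p-values and standard errors (SE) in the report come from these limma fits.

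The genes named follow a rule fixed before the data were examined, as were the comparisons, the lists and the alternatives other than those named as added. The rule takes Mbd3, then the 10 largest rises and the 10 largest falls among genes that passed and changed the same way in every line (for a class difference, with no overlap between the classes), then up to 4 members with the largest change from each list. Of these list members the text names a part, picked with their values in view, and Tdgf1 is named in the report outside the rule. How often calls were kept under the alternatives is counted over all genes the rule takes and all named besides. Where no gene passed, the rule takes the 5 smallest p-values on each side, and for single arrays the 10 largest differences on each side, of which the text names a part. Predicted genes, clones, microRNAs and receptor segments are counted but not named.

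The 19 lists were naive and general pluripotency, LIF and STAT3 targets, primed and formative epiblast, primitive and extraembryonic endoderm, gastrulation mesoderm, neuroectoderm, trophectoderm and trophoblast, mesenchyme and extracellular matrix, cardiac and muscle, blood and endothelium, germline and meiosis, 2-cell-like state, NuRD subunits, cell cycle, p53 targets, imprinted genes, polycomb-silenced HOX and homeobox genes, fibroblast feeder layer, and glycolysis and hypoxia. They were written from general knowledge and some share members. Counts per list use the adjustment over all genes, and then again an adjustment over the list alone. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at the estimated correlation, and with fry, each adjusted over the 19 lists of a comparison. Camera compares a list with the other genes. Fry tests whether the list moved on balance one way, its mixed form whether members moved in either direction, and neither compares with other genes. Over the 10 comparisons camera called 73 lists with the preset correlation, 0 of these 73 with the estimated correlation and 37 of them by fry. In 17 of 190 pairs of list and comparison the median, the mean and the direction of camera differed in sign; 0 of these was a camera call, and the largest median among them was 0.11.

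Per line, the SD of the response over tested genes, the mean response of 3 lists, the correlation of the response with that of EBRTcH3 and the position between the empty vector line and EBRTcH3 were compared between the classes with two-sided exact permutation tests, adjusted over these 6. Comparisons of 1 array with 1 array have no test; their list medians were set against 10000 random lists with the same number of genes and similar signal. Chromosome medians used genes with a mean log2 signal over 7, each line against the median of the 7 lines made from EBRTcH3, less the median of the other autosomes.

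The limma fits were tested on simulated data with 200 changed genes of 22872. At a 4-fold change 99% to 100% were recovered in each of the 10 comparisons. At 2-fold, 99% were recovered for LIF withdrawal over all lines, 99% in the retaining lines, 96% in the lacking lines, 90% for the class difference in response, 98% and 96% for the class difference with and without LIF, 96% for the MBD deletion in either condition, and 98% and 99% for the coiled-coil deletion with and without LIF. False calls made up 2.5% to 9.7% of the calls.

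The alternatives tried were no filter and a filter at the 60th percentile, the mean of a gene's probe sets, quantile normalization, median centring, robust and trended moderation, a 2-fold minimum, and array weights. Others were the run of array titles as a covariate and each run alone, each line left out, unpaired fits, a fit of all 16 arrays with the line as a random block (statmod 1.5.0), other correlation measures and fold limits for the single-array comparisons. Added after the data were seen were a fit with the genes of chromosomes 8, 14, 15 and Y left out and every choice of 3 retaining lines. Probe sets with several symbols or none, raw intensities and exon-level signals were not used here.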

Results

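Expression was measured on 16 Affymetrix arrays, 1 for each of 8 mouse embryonic stem cell (ESC) lines in each of 2 culture conditions. EBRTcH3, a male ESC line of the 129SV strain, served as the wild type. The 7 other lines were made from it by removing MBD3, a subunit of the nucleosome remodelling and deacetylase complex NuRD, and stably adding a vector. The vector encoded MBD3a, MBD3b, MBD3c, MBD3a without its methyl-CpG-binding domain (MBD-deleted), MBD3a without its coiled coil (coiled-coil-deleted), MBD3a without both (doubly deleted), or nothing (empty vector). Each line was grown with leukaemia inhibitory factor (LIF), which maintains self-renewal of mouse ESCs through STAT3, and for 12 days without it. The comparisons set 5 lines that retain a coiled coil (EBRTcH3, MBD3a, MBD3b, MBD3c, MBD-deleted) against 3 that lack it (empty vector, coiled-coil-deleted, doubly deleted). The labels name no second culture of any line in a condition, so the lines serve as replicates and the p-values measure the spread between these lines. The number of arrays limits the precision.

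Mbd3, the targeted gene, was lowest in the empty vector line. Its log2 signal with and without LIF was 9.10 and 9.17 in EBRTcH3, 9.09 and 8.96 in MBD3a, 9.15 and 9.59 in MBD3b, 8.65 and 8.57 in MBD3c and 8.96 and 8.56 in MBD-deleted. It was 9.12 and 9.02 in coiled-coil-deleted, 8.48 and 8.45 in doubly deleted, and 7.00 and 7.45 in the empty vector line. The empty vector line lay 4.29-fold below EBRTcH3 with LIF and 3.29-fold below it without. The lowest construct line lay 1.48 and 1.00 log2 above the empty vector line. Which exons the Mbd3 probe set covers is not given in the sources used here. Mbd3 did not pass in any of the limma comparisons below with all lines in the fit. Lacking minus retaining lines with LIF, it passed without coiled-coil-deleted (-1.25 log2, adjusted p = 0.0376).

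LIF withdrawal and the class of line gave the 2 largest axes of variation. The first principal component (43% of the variance) moved with LIF withdrawal by 76.6 in EBRTcH3, 76.5 in MBD3a, 78.1 in MBD3b, 80.8 in MBD3c and 57.8 in MBD-deleted. The same shift was 28.9 in the empty vector line, 14.6 in coiled-coil-deleted and 12.8 in doubly deleted. The second component (22.4%) set the 3 lines without a coiled coil apart from the other 5 in both conditions.

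**Figure D1:**
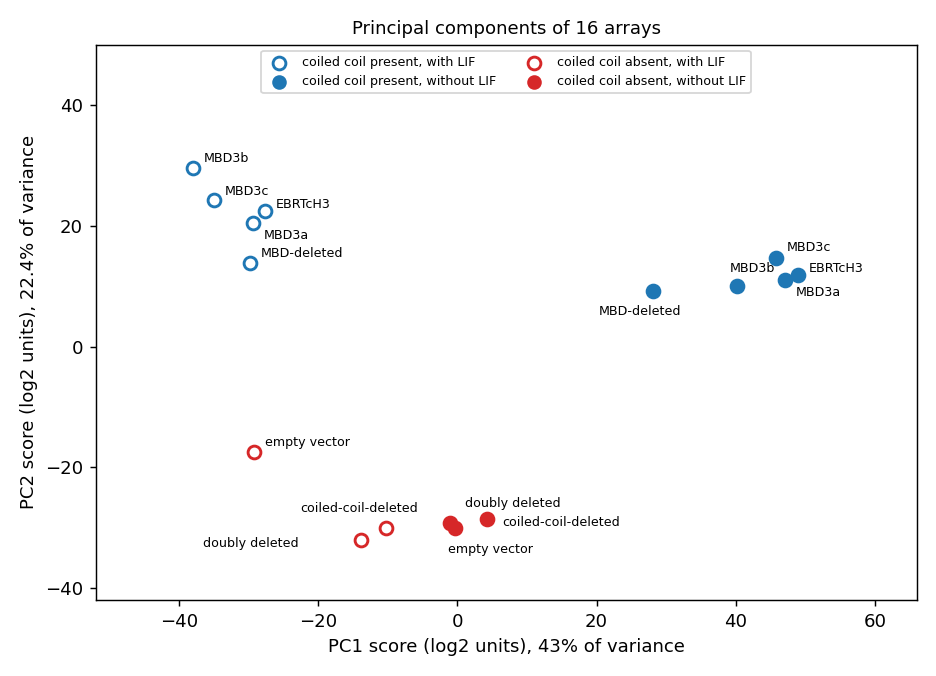
The first 2 principal components of the 16 arrays. Open circles, with LIF; filled circles, without LIF; blue, lines that retain a coiled coil; red, lines that lack it.

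Over all 8 lines, LIF withdrawal lowered the naive pluripotency factor Klf4 and raised the imprinted growth factor gene Igf2, the smooth muscle actin-binding protein gene Tagln and the simple-epithelium keratins Krt18 and Krt8. Klf4, a direct target of STAT3, fell by 2.17 ± 0.13 log2 (SE, n = 8 lines, adjusted p = 2.71e-05) and Pros1, which encodes the anticoagulant protein S, by 2.07 ± 0.10 (adjusted p = 9.22e-06). Igf2 rose by 3.81 ± 0.61 (adjusted p = 0.00237), Tagln by 3.63 ± 0.61, Thbs1 by 3.55 ± 0.42, the carbonic anhydrase gene Car4 by 3.37 ± 0.32 and the iron exporter gene Slc40a1 by 3.09 ± 0.27 (adjusted p = 0.000182). Gbp2 (3.45), Krt18 (3.25), Acta2 (3.15), Krt8 (3.06) and Fndc3c1 (3.00) complete the 10 largest rises. The largest falls also held Serpinb6c (-2.58), Inhbe (-2.44), Nupr1 (-2.27), Mras (-2.21), Aldh1l2 (-2.14), Chac1 (-1.99), B4galnt2 (-1.91) and Txnip (-1.90). In all, 5715 genes passed (3452 higher, 2263 lower), 550 of them at least 2-fold. Among list members, 17 of 28 pluripotency genes fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 8.88e-09, adjusted p = 0.466 with an estimated correlation). Of 24 trophectoderm genes 20 rose and 0 fell (camera adjusted p = 2.96e-08, adjusted p = 0.374 with an estimated correlation). Also called by camera were LIF and STAT3 targets (median -0.76), primed epiblast (0.80), mesenchyme (0.44), 2-cell-like (0.68), imprinted (0.64) and feeder genes (0.31). Their adjusted p was 1.04e-06, 6.43e-05, 0.00145, 0.00258, 0.000333 and 0.0208 (adjusted p = 0.0727, 0.484, 0.513, 0.484, 0.484 and 0.484 with an estimated correlation). The count was 3645 without MBD3c, 3761 without MBD3a and 18 within the second run of array titles (3 lines).

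In the 5 lines that retain a coiled coil, LIF withdrawal raised Igf2, Tagln, Krt18 and Thbs1 and lowered Hhip and Serpinb6c. Tagln rose by 5.15 ± 0.13 log2 (SE, n = 5 lines; 35.5-fold, adjusted p = 2.19e-09), the smooth muscle actin gene Acta2 by 4.49 ± 0.16 and the matrix protein gene Thbs1 by 4.57 ± 0.16. Krt18 rose by 4.76 ± 0.19 (27-fold), Krt8 by 4.28 ± 0.16 and Igf2 by 5.28 ± 0.25 (38.8-fold, adjusted p = 1.25e-07). The largest rises also included the interferon-inducible GTPase gene Gbp2 (4.87 ± 0.24), the myelin protein gene Pmp22 (4.59 ± 0.21), Fndc3c1 (4.31 ± 0.17) and Car4 (4.13 ± 0.16). The largest falls were in the hedgehog-binding protein gene Hhip (-3.83 ± 0.32, adjusted p = 6.02e-06), the protease inhibitor gene Serpinb6c (-3.45 ± 0.22), Inhbe, which encodes an activin subunit (-3.18 ± 0.21), and the stress-response gene Nupr1 (-3.02 ± 0.18). Napsa (-2.84 ± 0.13), the mitochondrial folate enzyme gene Aldh1l2 (-2.83 ± 0.20), the RAS relative Mras (-2.75 ± 0.10), the cholesterol transporter gene Abca1 (-2.70 ± 0.20), Aqp3 (-2.65 ± 0.14) and Zeb1 (-2.44 ± 0.22) also fell. In all, 8181 genes passed (4870 higher, 3311 lower), 1179 of them at least 2-fold.

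Among the fixed lists in these 5 lines, 21 of 28 naive and general pluripotency genes fell and 3 rose (23 and 3 adjusted over the list alone). Klf4 changed by -2.44 ± 0.10 (adjusted p = 4.96e-08), Nr0b1 by -2.32 ± 0.17 and Tbx3 by -1.95 ± 0.12. Of 14 LIF and STAT3 targets 10 fell and 3 rose (10 and 3 adjusted over the list alone); Ier3, an immediate early gene, rose by 1.89 ± 0.18. Of 16 primed and formative epiblast genes 12 rose and 1 fell (12 and 1 adjusted over the list alone). Fgf5, the standard marker of that state, rose by 2.94 ± 0.17 (7.67-fold, adjusted p = 3.86e-07), the tight junction gene Cldn6 by 2.70 ± 0.14 and the Wnt effector Lef1 by 2.63 ± 0.14. Of 24 trophectoderm and trophoblast genes 18 rose and 1 fell (20 and 1 adjusted over the list alone), among them Krt19 (3.81 ± 0.14) and Hand1 (3.45 ± 0.34). Of 27 mesenchyme and extracellular matrix genes 17 rose and 2 fell (19 and 2 adjusted over the list alone). Of 20 imprinted genes 15 rose and 3 fell (15 and 3 adjusted over the list alone), with Peg10 at 2.36 ± 0.09 and the cyclin-dependent kinase inhibitor gene Cdkn1c at 1.98. The camera adjusted p was 4.36e-10 for pluripotency, 0.000239 for LIF and STAT3 targets, 1.33e-05 for primed epiblast, 8.2e-09 for trophectoderm, 1.38e-05 for mesenchyme and 2.79e-05 for imprinted genes. For each of the 6 it was adjusted p = 0.279 with an estimated correlation.

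In the same 5 lines, camera also called the gastrulation, 2-cell-like, feeder and glycolysis lists (medians 0.31, 0.96, 0.55 and 0.69). Of 19 gastrulation mesoderm genes 6 rose and 1 fell (9 and 1 adjusted over the list alone), including Mixl1 (2.59 ± 0.28) and Eomes (1.58 ± 0.17). Of 13 genes of the 2-cell-like state 7 rose and 1 fell (12 and 1 adjusted over the list alone), including Zscan4f (1.69 ± 0.52, adjusted p = 0.0251) and Zscan4d (1.63 ± 0.37). Of 8 fibroblast feeder genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), with Cd44 at 1.95 ± 0.15 and Dcn at 1.05 ± 0.12, alongside the mesenchyme genes. The labels name no feeder layer. Of 19 glycolysis and hypoxia genes 13 rose and 3 fell (13 and 4 adjusted over the list alone), with Bnip3 at 1.86 and the glucose transporter gene Slc2a1 at 1.71 ± 0.18. With camera, adjusted p was 0.0167 for mesoderm, 0.0103 for 2-cell-like genes, 0.00636 for feeder genes and 0.016 for glycolysis (adjusted p = 0.535, 0.485, 0.279 and 0.506 with an estimated correlation). Without EBRTcH3 the mesoderm call was lost (adjusted p = 0.0647), as was that of Zscan4f without MBD3a (1.64), MBD3b (1.55), MBD3c (1.56) or MBD-deleted (1.59).

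The 9 remaining lists gave no camera call in these 5 lines, although each held genes that moved. Endoderm genes went both ways (14 rose and 7 fell of 28, the same adjusted over the list alone; camera adjusted p = 0.101, fry adjusted p = 9.28e-05), with Dab2 at 2.70 ± 0.13 and Cited1 at 2.47. In the neuroectoderm list 6 rose and 5 fell of 24 (6 and 5 adjusted over the list alone), with nestin (Nes) at 1.90, Sox11 at 1.86 and the neural transcription factor Pax6 at -1.75 ± 0.17. The NuRD list had 5 of 13 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.142, fry adjusted p = 0.000149), with Cdk2ap1 at 0.89 and Mta1 at 0.85 ± 0.08. In the cardiac and muscle list 7 of 23 rose and 2 fell (8 and 2 adjusted over the list alone), with Tbx20 at 1.87. The blood and endothelium list had 6 of 20 higher and 1 lower (6 and 1 adjusted over the list alone), with the VEGF receptor gene Flt1 at 2.19. In the germline and meiosis list 3 of 23 rose and 6 fell (3 and 6 adjusted over the list alone), with the synaptonemal complex gene Sycp3 at -1.83 ± 0.22. The HOX and homeobox list had 7 of 22 higher and 1 lower (7 and 1 adjusted over the list alone), with Msx2 at 1.81 ± 0.27. The cell cycle list had 4 of 22 higher and 6 lower (4 and 6 adjusted over the list alone), with Kif11 at -0.70. In the p53 target list 4 of 17 rose and 5 fell (4 and 5 adjusted over the list alone), with Perp at 1.62. The median of that list was 0.09 while camera pointed down (adjusted p = 0.95). With 1 line left out camera called the germline list without MBD3b (-0.23, adjusted p = 0.0128) or MBD-deleted (-0.24, adjusted p = 0.0289) and the HOX list without MBD-deleted (0.35, adjusted p = 0.0234).

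In the 3 lines that lack a coiled coil, LIF withdrawal lowered Socs3, Klf4 and Bcl3 and raised Id2, Klhl13 and Car4. Socs3, the feedback inhibitor of that pathway, fell by 1.87 ± 0.13 log2 (SE, n = 3 lines; 3.66-fold, adjusted p = 0.000104), Klf4 by 1.73 ± 0.13 (3.32-fold, adjusted p = 0.000113) and Bcl3 by 1.49 ± 0.19. Other large falls were in the redox regulator gene Txnip (-2.28 ± 0.21), Pros1 (-2.18 ± 0.16), the amino acid transporter genes Slc38a5 (-1.97 ± 0.17) and Slc1a1 (-1.91 ± 0.22). The protease inhibitor gene A2m (-1.80 ± 0.15), the prohormone-processing gene Cpe (-1.72 ± 0.16), Kdelr3 (-1.69 ± 0.14) and Chac1 (-1.66 ± 0.28) fell too. These SEs pool the spread of all 8 lines in 1 fit. Over the 3 lines alone the SD of the response was 0.33 for Socs3, 0.25 for Klf4, 0.73 for Txnip and 0.86 for Chac1. The largest rises were in Id2, an inhibitor of basic helix-loop-helix factors (2.44 ± 0.16, 5.43-fold, adjusted p = 6.92e-05), Klhl13 (2.23 ± 0.14), Car4 (2.12 ± 0.21) and Slc40a1 (2.00 ± 0.14). They also held the noncoding RNA gene Platr30 (2.00 ± 0.20), the vitamin C transporter gene Slc23a1 (1.92 ± 0.30), Sfmbt2 (1.88 ± 0.14), Thbs1 (1.85 ± 0.21), the X-linked homeobox gene Rhox5 (1.80 ± 0.27) and Gpat3 (1.75 ± 0.26). Fgf5 rose by 1.45 ± 0.21 (2.73-fold) and Elf5, a trophoblast transcription factor, by 1.32 ± 0.12. Without the empty vector line Chac1, Gpat3, Rhox5 and Slc23a1 no longer passed (-1.17, 1.68, 1.52 and 2.01; adjusted p = 0.0787, 0.0714, 0.076 and 0.064), nor did Slc23a1 without coiled-coil-deleted (1.62, adjusted p = 0.0599).

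By list, 8 of 14 LIF and STAT3 targets fell and 0 rose in these 3 lines (10 and 1 adjusted over the list alone; camera adjusted p = 1.9e-12, adjusted p = 0.0639 with an estimated correlation). Of 28 pluripotency genes 5 fell and 0 rose (8 and 1 adjusted over the list alone), of which Klf4, Tbx3 (-1.26 ± 0.15), Tfcp2l1 (-1.16 ± 0.18) and Klf5 (-0.87) are also on that list and Tdgf1 (-0.74), named after its value was seen, is not. Of 16 primed epiblast genes 4 rose and 1 fell (8 and 2 adjusted over the list alone). Of 24 trophectoderm genes 6 rose and 0 fell (11 and 0 adjusted over the list alone), with Krt8 at 1.02 ± 0.21 (adjusted p = 0.0244). For these 3 lists camera adjusted p was 2.36e-05, 0.000168 and 3.61e-10 (adjusted p = 0.628, 0.367 and 0.367 with an estimated correlation). In the mesenchyme list 3 of 27 rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.272), among them Tagln (1.09 ± 0.16) and Acta2 (0.92 ± 0.21, adjusted p = 0.0442). Several of these calls were lost with 1 line left out, most of them at a similar change. Without the empty vector line Klf5 (-0.72), Tfcp2l1 (-1.12), Tdgf1 (-0.77), Krt8 (1.01), Tagln (1.14) and Acta2 (0.85) no longer passed. The same held without coiled-coil-deleted for Tdgf1 (-0.74), Krt8 (0.90) and Acta2 (0.73), without doubly deleted for Tfcp2l1 (-1.10), Tdgf1 (-0.72) and Krt8 (1.15), and for Acta2 without EBRTcH3, MBD3b or MBD3c (0.92 each). Camera also called the NuRD list (0 of 13 passed, median 0.12, adjusted p = 0.0261) and the imprinted list (1 rose and 2 fell of 20, median 0.21, adjusted p = 0.0193), with adjusted p = 0.367 and 0.423 at an estimated correlation. Both calls were lost without coiled-coil-deleted (adjusted p = 0.134 and 0.0576) or doubly deleted (adjusted p = 0.142 and 0.074). In the feeder list 0 of 8 passed (median 0.00), in limma as in camera (adjusted p = 0.659). In all, 670 genes passed (391 higher, 279 lower), 151 of them at least 2-fold, and 3603 had an unadjusted p under 0.05. The count was 114 without the empty vector line, 266 without coiled-coil-deleted, 280 without doubly deleted and 1039 without MBD-deleted. It was 1117 with the title run as covariate, 1611 with array weights, 84 within the first run of titles and 0 within the second. With 3 of the 5 retaining lines at a time, 4681 to 7244 genes passed there and 365 to 1067 in the 3 lacking lines (10 choices, added after the data were seen).

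The response to LIF withdrawal differed between the 2 classes of line, with Pmp22, Tagln, Krt18 and Igf2 among the genes that differed most. Pmp22 rose by 4.59 ± 0.73 (SD, n = 5 lines) where a coiled coil was retained and its response was 0.25 ± 0.18 (SD, n = 3 lines) where it was lacking. For Tagln the 2 means were 5.15 ± 0.30 and 1.09 ± 0.39, a difference of -4.06 ± 0.21 (SE, adjusted p = 5.26e-06). They were 4.76 ± 0.58 and 0.75 ± 0.44 for Krt18 and, for Igf2, 5.28 ± 0.86 and 1.35 ± 0.38. The NADPH oxidase gene Nox4 differed by -3.24 ± 0.13 (adjusted p = 1.09e-06), Gbp2 by -3.79 ± 0.39, Acta2 by -3.58 ± 0.27, Fndc3c1 by -3.51 ± 0.27, Krt8 by -3.26 ± 0.26 and the proteoglycan gene Bgn by -3.20 ± 0.25. In the other direction, Hhip responded by -3.83 ± 0.87 and -0.26 ± 1.09. Nr0b1, which is on the pluripotency list, responded by -2.32 ± 0.54 and -0.16 ± 0.24 (difference 2.16 ± 0.27, adjusted p = 0.000785). Napsa (2.41 ± 0.21), Serpinb6c (2.31 ± 0.36), Abca1 (2.24 ± 0.33), Capn3 (2.20 ± 0.29), Cd80 (2.19 ± 0.54, adjusted p = 0.0241), Krtdap (2.16 ± 0.41), Mmrn2 (2.14 ± 0.30) and Septin1 (2.06 ± 0.21) also had a higher response in the lacking lines. Abca1 and Nr0b1 were already lower with LIF in the lacking lines, as given below. The Cd80 call was lost without the empty vector line (2.05), MBD3a (1.98), MBD3b (2.12), coiled-coil-deleted (2.37) or doubly deleted (2.16). In all, 2760 genes differed (953 with a higher response in the lacking lines, 1807 with a lower one), 886 of them at least 2-fold.

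**Figure D2:**
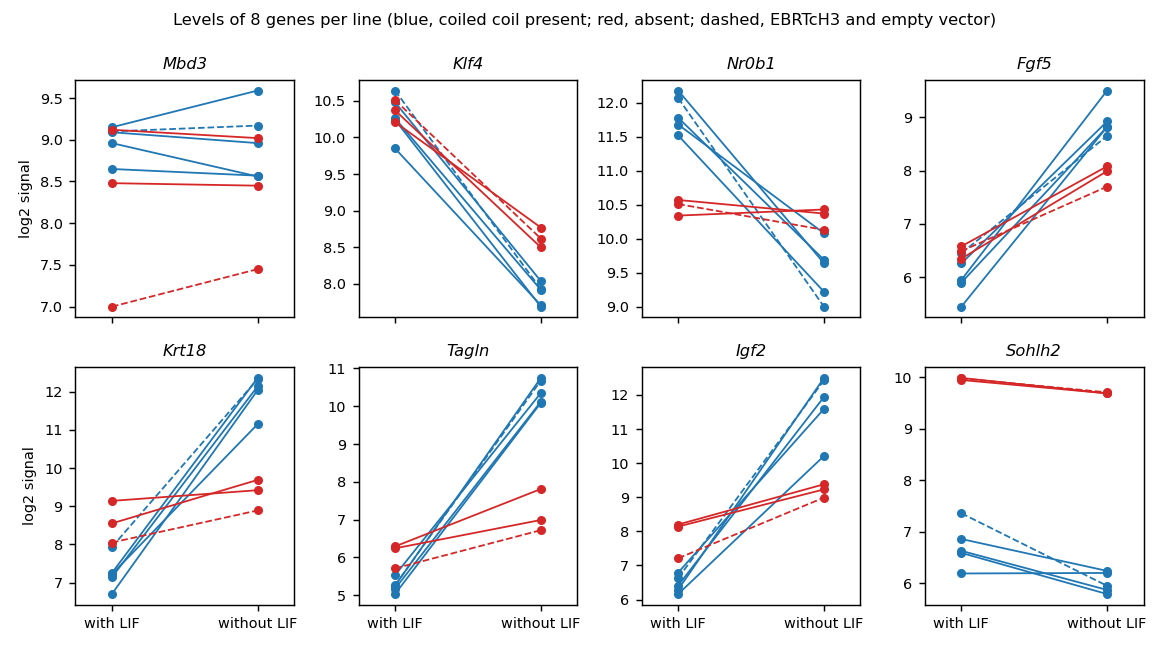
Log2 signal of 8 genes in each line with and without LIF. Blue, coiled coil retained; red, lacking; dashed, EBRTcH3 and the empty vector line.

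Of 28 pluripotency genes, 11 had a higher response in the lacking lines and 2 a lower one (19 and 2 adjusted over the list alone). Esrrb, an orphan nuclear receptor of the naive state, differed by 1.18 ± 0.20, Prdm14 by 1.11 and Dppa3 by -1.28 ± 0.33. The response was lower in the lacking lines for 13 of 27 mesenchyme genes and higher for 2 (15 and 2 adjusted over the list alone). It was lower for 13 of 24 trophectoderm genes and higher for 3 (14 and 3 adjusted over the list alone). It was lower for 9 of 20 imprinted genes and higher for 1 (12 and 2 adjusted over the list alone), with Cdkn1c at -1.76 and Peg10 at -1.44 ± 0.14. It was lower for 10 of 28 endoderm genes and higher for 1 (13 and 3 adjusted over the list alone), with Dab2 at -2.09 ± 0.21. For 6 of 16 primed epiblast genes it was lower (9 adjusted over the list alone), with Cldn6 at -2.13 ± 0.23 and Fgf5 at -1.49 ± 0.27. Feeder genes moved beside these lists: 3 of 8 had a lower response (3 adjusted over the list alone), with Cd44 at -1.82 ± 0.25. By camera, adjusted p was 1.27e-07 for pluripotency, 3.06e-06 for mesenchyme, 0.000281 for trophectoderm, 1.48e-05 for imprinted, 0.00448 for endoderm, 1.23e-05 for primed epiblast and 0.00883 for feeder genes (adjusted p = 0.463, 0.282, 0.471, 0.282, 0.282, 0.282 and 0.415 with an estimated correlation). Camera also called glycolysis (8 of 19 lower, 0 higher, median -0.63, adjusted p = 0.00134), mesoderm (3 of 19 lower, 0 higher, median -0.39, adjusted p = 0.00607) and cell cycle genes (2 of 22 higher, 1 lower, median 0.09, adjusted p = 0.0441). With an estimated correlation these had adjusted p = 0.471, 0.622 and 0.471. The cell cycle call was lost without EBRTcH3 (adjusted p = 0.0661), MBD3a (adjusted p = 0.0613), MBD3b (adjusted p = 0.0789) or doubly deleted (adjusted p = 0.285). Fry called 7 lists, which did not include pluripotency, glycolysis, mesoderm or cell cycle genes (adjusted p = 0.0661, 0.0661, 0.128 and 0.106). For the LIF and STAT3 targets 3 of 14 were higher and 4 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.652). The Dppa3 call was lost without MBD3c (-1.16), the empty vector line (-1.27), coiled-coil-deleted (-1.43) or doubly deleted (-1.14), and that of Cdkn1c without coiled-coil-deleted (-1.53) or doubly deleted (-1.59).

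**Figure D3:**
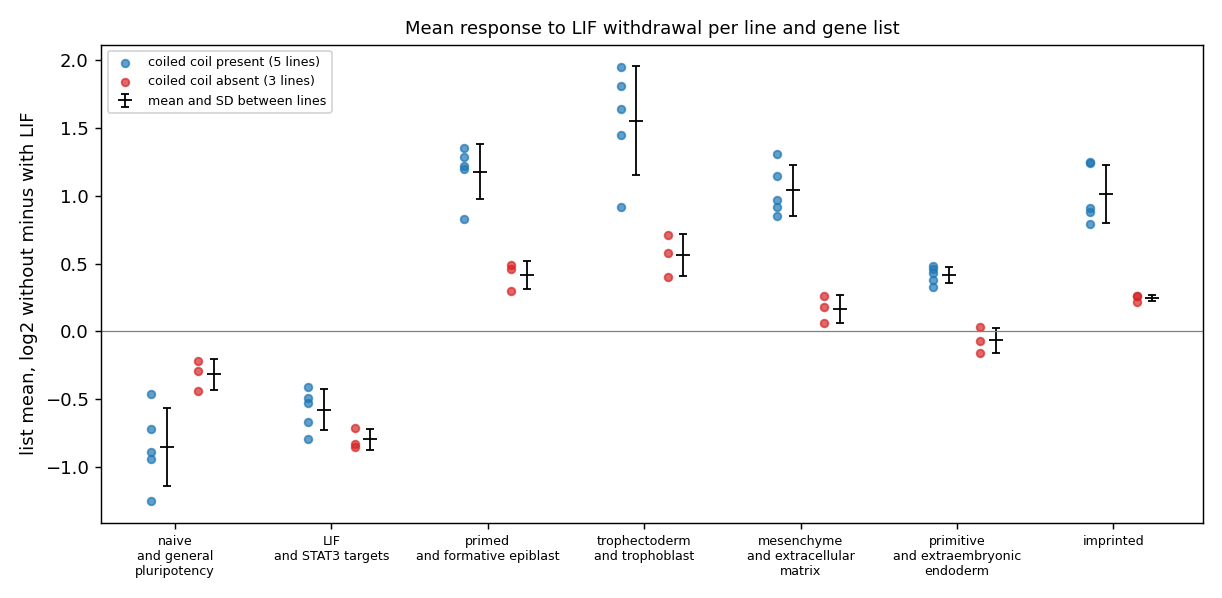
Mean response to LIF withdrawal of 7 gene lists in each line. Bars give the mean and the SD between lines.

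Measured per line, the responses of the 2 classes did not overlap in 8 of the 19 lists and overlapped in 11. The 3 lists chosen for a test are among the 8, with trophectoderm, primed epiblast, imprinted, feeder and blood genes. The 11 include mesoderm (0.01 in MBD-deleted, 0.15 in the empty vector line) and the 2-cell-like state (-0.02 in EBRTcH3, 1.33 in the empty vector line). The mean response of the pluripotency list was -1.254 in EBRTcH3, -0.943 in MBD3a, -0.723 in MBD3b, -0.885 in MBD3c and -0.455 in MBD-deleted, against -0.292 in the empty vector line, -0.22 in coiled-coil-deleted and -0.437 in doubly deleted. The class means were -0.852 ± 0.294 and -0.316 ± 0.110 (SD, n = 5 and 3 lines) for pluripotency, 0.418 ± 0.060 and -0.065 ± 0.096 for endoderm, and 1.038 ± 0.187 and 0.17 ± 0.1 for mesenchyme. The SD of the response over all genes was 0.549 ± 0.030 and 0.332 ± 0.042. Each of these 4 differences had an exact permutation p = 0.0357, the smallest that 56 splits can give (adjusted p = 0.0536 over 6 tests). After median centring the pluripotency difference had an exact permutation p = 0.0714. The correlation of a line's response with that of EBRTcH3 was 0.816 in MBD3a, 0.775 in MBD3b, 0.786 in MBD3c and 0.605 in MBD-deleted. In the empty vector, coiled-coil-deleted and doubly deleted lines it was 0.431, 0.246 and 0.188 (exact permutation p = 0.0571, the smallest that 35 splits can give). At least 2-fold responses numbered 1650 genes in EBRTcH3, 1531 in MBD3a, 1639 in MBD3b, 1690 in MBD3c and 1140 in MBD-deleted, against 445, 238 and 363 in the empty vector, coiled-coil-deleted and doubly deleted lines.

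The numbers in the array titles form 2 runs, and the labels do not say whether these are batches: EBRTcH3, MBD3a, MBD3b, MBD3c and the empty vector line are in the first and the other 3 lines in the second. The class difference in response correlated at r = 0.563 across genes between the runs, which share no array, and 95.9% of the genes called in the first run alone had the same sign in the second (63.9% of all genes). The first run alone gave 732 calls and the second 0. In the first run the lacking class is the empty vector line alone and in the second the retaining class is MBD-deleted alone, so the calls within a run take their spread from the other class. The count of 2760 was 1353 without coiled-coil-deleted, 1369 without doubly deleted and 5414 with array weights.

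With LIF, the lines that lack a coiled coil had higher levels of Slc38a5, Sohlh2 and the PRAME family genes Pramel14 and Pramel30 and lower levels of Pax6 and Sycp3. Sohlh2, a germ cell helix-loop-helix factor, stood at 6.73 ± 0.43 (SD, n = 5 lines) where a coiled coil was retained and 9.97 ± 0.02 (SD, n = 3 lines) where it was lacking (difference 3.25 ± 0.21, SE, adjusted p = 1.05e-05). Pramel14 differed by 3.46 ± 0.18, its relative Pramel30 by 3.25 ± 0.23 and Slc38a5 by 3.45 ± 0.11 (adjusted p = 1.19e-07). The proteoglycan gene Srgn differed by 3.16 ± 0.29, the glutathione peroxidase gene Gpx2 by 2.96 ± 0.27, Ccdc152 by 2.78 ± 0.19, the serine protease gene Htra1 by 2.73 ± 0.28, Gcnt4 by 2.53 ± 0.19 and the ectonucleotidase gene Entpd1 by 2.47 ± 0.20. Lower in the lacking lines were Abca1 (-2.41 ± 0.32), Glod5 (-2.28 ± 0.11), the synaptonemal complex gene Sycp3 (-2.26 ± 0.22), Pax6 (-2.21 ± 0.13, adjusted p = 6.31e-06), and Hmgn5 (-2.11 ± 0.15). So were Cnppd1 (-2.07 ± 0.16), Kcnt2 (-2.05 ± 0.23), Gstm2 (-1.99 ± 0.23), the antiviral gene Ifitm3 (-1.92 ± 0.25) and Sfmbt2 (-1.87 ± 0.16). Pairs of near-identical genes, such as Pramel14 and Pramel30, were not told apart beyond their probe sets.

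Of 28 pluripotency genes 6 were lower in the lacking lines and 2 higher (8 and 4 adjusted over the list alone), with Nr0b1 at -1.37 ± 0.15 and Nanog at -0.51 ± 0.15 (adjusted p = 0.0453). Of 16 primed epiblast genes 6 were higher (6 adjusted over the list alone), with the DNA methyltransferase gene Dnmt3a at 1.10 ± 0.17. Of 24 trophectoderm genes 6 were higher and 1 lower (7 and 2 adjusted over the list alone), with Krt19 at 1.5 ± 0.18 and Krt18 at 1.33 ± 0.27. Of 19 glycolysis and hypoxia genes 7 were higher and 1 lower (10 and 2 adjusted over the list alone). Of 20 imprinted genes 2 were higher and 6 lower (2 and 6 adjusted over the list alone), with Igf2 at 1.39 ± 0.22 and Peg3 at -1.37 ± 0.23. Mesoderm genes included Eomes at 1.89 ± 0.13 (3 of 19 higher, 1 lower; 4 and 1 adjusted over the list alone). Adjusted p by camera was 0.0316 for pluripotency and primed epiblast, 0.0438 for trophectoderm and 0.038 for glycolysis, imprinted and mesoderm genes (adjusted p = 0.737 for each of them with an estimated correlation). It was 0.038 for blood and endothelium (3 of 20 higher, 0 lower, median 0.20) and 0.0438 for p53 targets (1 of 17 higher, 3 lower, median -0.11), and adjusted p = 0.737 and 0.778 with an estimated correlation. The blood call was lost without coiled-coil-deleted or doubly deleted (adjusted p = 0.0592 and 0.0924). That of the p53 targets was lost without EBRTcH3, MBD3b, MBD3c, the empty vector line or doubly deleted (adjusted p = 0.168, 0.0908, 0.0696, 0.12 and 0.12). Without coiled-coil-deleted camera called 2 further lists, germline (-0.10, adjusted p = 0.0485) and 2-cell-like genes (-0.46, adjusted p = 3.69e-06). The trophectoderm call was lost without MBD3c, coiled-coil-deleted, MBD-deleted or doubly deleted (adjusted p = 0.067, 0.0592, 0.0794 and 0.0818) and the glycolysis call without the empty vector line, MBD3a or doubly deleted (adjusted p = 0.051, 0.0623 and 0.0689). The imprinted call was lost without the empty vector line or doubly deleted (adjusted p = 0.051 and 0.0689) and the mesoderm call without doubly deleted (adjusted p = 0.0933). Nanog no longer passed without EBRTcH3 (-0.46), MBD3a (-0.48), MBD3b (-0.55), MBD-deleted (-0.46), the empty vector line (-0.44) or coiled-coil-deleted (-0.45). In all, 3233 genes differed (1750 higher, 1483 lower), 502 of them at least 2-fold. The count was 1779 without coiled-coil-deleted, 1852 without doubly deleted, 5373 with array weights, 680 within the first run of titles and 0 within the second; the difference correlated at r = 0.574 between the runs.

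Without LIF, the lines that lack a coiled coil had higher levels of Sohlh2, Nlrp4f and Pramel14 and lower levels of Tagln, Fndc3c1 and Pmp22 than the lines that retain it. Tagln stood at 10.40 ± 0.31 (SD, n = 5 lines) and 7.17 ± 0.57 (SD, n = 3 lines), a difference of -3.22 ± 0.24 (SE, adjusted p = 2.43e-05). Fndc3c1 differed by -3.65 ± 0.13 (adjusted p = 1.01e-06), Pmp22 by -3.23 ± 0.44, and Gbp2 by -3.22 ± 0.42. The semaphorin genes Sema6a and Sema3e differed by -3.18 ± 0.18 and -2.95 ± 0.11, the scavenger receptor gene Colec12 by -3.15 ± 0.22, Vwa5a by -3.15 ± 0.26, Acta2 by -3.13 ± 0.26 and Vgll3 by -2.83 ± 0.34. Sohlh2 was higher in the lacking lines by 3.69 ± 0.11 (adjusted p = 4.83e-07), Nlrp4f, of a family active in oocytes, by 3.83 ± 0.26, Pramel14 by 3.74 ± 0.29 and Pramel30 by 3.42 ± 0.22. Also higher were Gpr83 by 3.49 ± 0.20, Srgn by 3.19 ± 0.14, the costimulatory ligand gene Cd80 by 3.16 ± 0.25, Gpx2 by 3.02 ± 0.18, its pseudogene Gpx2-ps1 by 2.81 ± 0.14 and Ccdc141 by 2.53 ± 0.13. In all, 4791 genes differed (1955 higher, 2836 lower), 754 of them at least 2-fold.

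Of 28 pluripotency genes 12 were higher in the lacking lines without LIF and 2 lower (17 and 2 adjusted over the list alone). Tbx3 differed by 1.17 ± 0.30, Tfcp2l1 by 1.07 ± 0.10, Esrrb by 1.02 ± 0.16 and Dppa3, a maternal factor, by -2.08 ± 0.15. The Tbx3 call was lost without the empty vector line (1.19), coiled-coil-deleted (1.13) or doubly deleted (1.18). Of 27 mesenchyme genes 14 were lower and 1 higher (18 and 1 adjusted over the list alone). Of 20 imprinted genes 14 were lower and 1 higher (15 and 2 adjusted over the list alone), with Igf2 at -2.53 ± 0.44, Usp29 at -2.28 ± 0.40, Peg3 at -2.23 ± 0.34 and Zim1 at -2.09 ± 0.35. Of 24 trophectoderm genes 10 were lower and 2 higher (11 and 2 adjusted over the list alone), with Krt18 at -2.67 ± 0.27 and the trophectoderm factor Cdx2 at -2.36 ± 0.42. Of 16 primed epiblast genes 7 were lower and 3 higher (10 and 3 adjusted over the list alone), with Pim2 at -1.87 ± 0.11 and the DNA methyltransferase gene Dnmt3b at -1.27 ± 0.10. Of 22 cell cycle genes 4 were higher (4 adjusted over the list alone). Of 13 genes of the 2-cell-like state 4 were lower and 1 higher (7 and 1 adjusted over the list alone). The mean of that list was 5.23 in EBRTcH3, below the 5.3 to 5.5 of the lacking lines. It was 6.17 to 6.36 in the other retaining lines, so the class difference does not hold against the wild type. Feeder genes had 2 of 8 lower (3 adjusted over the list alone; camera adjusted p = 0.115), with Cd44 at -1.73 ± 0.26, beside the mesenchyme genes. The adjusted p of camera was 4.66e-05 for pluripotency, 3.01e-06 for mesenchyme, 7.8e-07 for imprinted, 0.0048 for trophectoderm, 0.0235 for primed epiblast, 0.00282 for cell cycle and 0.0142 for 2-cell-like genes (adjusted p = 0.53, 0.317, 0.317, 0.609, 0.53, 0.317 and 0.53 with an estimated correlation). Glycolysis genes were called too (1 of 19 higher, 5 lower, median -0.23, adjusted p = 0.029, adjusted p = 0.609 with an estimated correlation), but not without EBRTcH3 (adjusted p = 0.0531) or doubly deleted (adjusted p = 0.0704). The feeder list was called without MBD-deleted (-0.27, adjusted p = 0.0479). The count of 4791 was 3014 without doubly deleted, 1822 within the first run of titles and 0 within the second; the difference correlated at r = 0.657 between the runs.

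Deleting the coiled coil from MBD3a, alone or with the MBD, raised Pramel14, Pramel30 and Sohlh2 in both conditions. The 4 lines compared here are also part of the class comparison above, so genes shared by the 2 comparisons are in part built in. Across the 4 MBD3a constructs without LIF (2 with and 2 without the coiled coil), the deletion raised Pramel14 by 3.90 ± 0.22 log2 (SE, n = 4 lines), Pramel30 by 3.84 ± 0.18, Sohlh2 by 3.67 ± 0.15 (adjusted p = 0.000318) and Nlrp4f by 3.60 ± 0.25. It lowered Fndc3c1 (-3.54 ± 0.22), the sialyltransferase gene St6gal2 (-3.06 ± 0.17), Sema6a (-3.00 ± 0.16) and Acta2 (-2.91 ± 0.36). Of 20 imprinted genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), and of 27 mesenchyme genes 9 fell and 1 rose (11 and 1 adjusted over the list alone). Of 13 genes of the 2-cell-like state 7 fell and 0 rose (9 and 1 adjusted over the list alone), with Zscan4d at -2.13 ± 0.28 (adjusted p = 0.00644). Camera adjusted p was 7.69e-07, 1.84e-05 and 0.000143 for these 3 lists (adjusted p = 0.616 for each of them with an estimated correlation). The 5 other camera calls were pluripotency (median 0.22, adjusted p = 0.00389), primed epiblast (-0.30, adjusted p = 0.0193), trophectoderm (-0.53, adjusted p = 0.0154), cell cycle (0.12, adjusted p = 0.0153) and glycolysis (-0.22, adjusted p = 0.0194). With an estimated correlation primed epiblast had adjusted p = 0.616 and the other 4 adjusted p = 0.672. Fry called only mesenchyme (adjusted p = 0.0224). With LIF the deletion raised Slc38a5 by 3.58 ± 0.14, Sohlh2 by 3.24 ± 0.15, Pramel14 by 3.40 ± 0.22, Pramel30 by 3.33 ± 0.18 and Gpx2 by 3.28 ± 0.22. There it lowered Sycp3 (-2.59 ± 0.18), Gstm2 (-2.35 ± 0.18), Glod5 (-2.30 ± 0.18) and the lipoprotein receptor gene Vldlr (-2.28 ± 0.18). With LIF camera called primed epiblast (median 0.37, adjusted p = 0.0301) and blood genes (0.23, adjusted p = 0.0461; adjusted p = 0.87 for both with an estimated correlation), and fry called 0 lists. Of 20 imprinted genes 3 rose and 3 fell with LIF (4 and 7 adjusted over the list alone; median -0.18, camera adjusted p = 0.364), with Igf2 at 1.95 ± 0.42 (adjusted p = 0.0322; -2.05 without LIF) and Plagl1 at 1.24 ± 0.14. The counts were 2077 without LIF (675 higher, 1402 lower) and 2346 with LIF (1225 higher, 1121 lower). Both conditions were in 1 fit without a block by line, so the 2 arrays of a line counted as independent. The SEs are therefore pooled over both conditions. The fit leaves 2 residual degrees of freedom and assumes that the 2 deletions add up. MBD3a lies in the first run of titles while the other 3 constructs lie in the second.

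For the deletion of the MBD from MBD3a, limma called 0 genes in either condition, with 1644 genes at an unadjusted p under 0.05 without LIF and 3335 with LIF. The comparison averages the deletion with and without the coiled coil, on 2 residual degrees of freedom. It comes from the same fit, in which the 2 arrays of a line counted as independent. It does not show that the MBD is without effect. By single lines, responses of at least 2-fold numbered 1140 in MBD-deleted against 1531 in MBD3a. They numbered 363 in doubly deleted against 238 in coiled-coil-deleted. The smallest adjusted p was 0.686 without LIF, where the smallest unadjusted p-values belonged to Gbp2 (-1.16 ± 0.15 log2, SE, n = 4 lines), Ppp1r3b (-0.97), Rpl37rt (1.06 ± 0.16) and the apoptosis inhibitor gene Bcl2 (0.82 ± 0.13). With LIF it was 0.109, with the germ cell helicase gene Ddx4 at -1.09 ± 0.13, Neto2 at -1.01, the small nuclear RNA gene Rnu2-10 at 0.91 and the mitophagy gene Bnip3 at 1.01 ± 0.15. Camera called 8 lists without LIF and 5 with LIF, and fry called 0 in either condition. Without LIF these were trophectoderm (median -0.45, adjusted p = 5.63e-08), imprinted (-0.32, adjusted p = 4.44e-05), mesoderm (-0.26, adjusted p = 4.44e-05) and LIF and STAT3 targets (-0.31, adjusted p = 0.000709). The others were glycolysis (-0.17, adjusted p = 0.000738), mesenchyme (-0.12, adjusted p = 0.0169), pluripotency (0.11, adjusted p = 0.0213) and primed epiblast (-0.11, adjusted p = 0.0338). With an estimated correlation pluripotency had adjusted p = 0.852, glycolysis adjusted p = 0.653 and the other 6 adjusted p = 0.531. With LIF the germline list (median -0.36, camera adjusted p = 4.55e-06) and the 2-cell-like list (median -0.60, camera adjusted p = 1.91e-07) lay lower. Camera also called p53 targets (-0.26, adjusted p = 0.000252), cell cycle (-0.14, adjusted p = 0.000314) and glycolysis (0.18, adjusted p = 0.0126), and for all 5 it was adjusted p = 0.647 with an estimated correlation. Adjusted over the list alone, 10 germline genes were lower and 1 higher, and 8 of the 2-cell-like genes were lower. With robust and trended moderation limma called 407 genes with LIF, 77.4% of them higher.

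Compared array against array, the empty vector line differed from EBRTcH3 with LIF in Slc38a5 (3.14 log2 higher), Pramel14 (2.93), Pramel30 (2.84), Srgn (2.73), Nlrp4f (2.68) and Sohlh2 (2.62). It lay below EBRTcH3 in the Y-linked genes Uty (-5.05) and Eif2s3y (-4.06), Zscan4f (-2.67), Zscan4c (-2.49), Pax6 (-2.49), Ifitm3 (-2.42) and Vim (-2.25). Without LIF it lay above EBRTcH3 in Gpr83 (4.21), Sohlh2 (3.76), Nlrp4f (3.72), Cd80 (3.37) and Hhip (3.10) and below it in Gbp2 (-4.20), Pmp22 (-4.14), Tagln (-3.96), Colec12 (-3.87), Tgfb2 (-3.70), Cdx2 (-3.68), Usp29 (-3.64) and Acta2 (-3.54). These comparisons rest on 1 array each side and have no test, and random lists carry neither the spread between lines nor the co-regulation of genes within a list. Against 10000 random lists of similar signal, the pluripotency median without LIF (0.63) lay above all of them, while 3 and 4 of them reached those of the 2-cell-like (0.40) and germline lists (0.27). Those of imprinted (-1.22), trophectoderm (-0.96), mesenchyme (-0.86), HOX (-0.63), LIF target (-0.52), mesoderm (-0.47) and glycolysis genes (-0.39) lay below all of them. Without LIF the 2-cell-like list thus went the other way in this pair of arrays than between the classes (median -0.78) and in the coiled-coil deletion (-1.24). With LIF its median (-0.72) lay below all of the random lists, as did those of p53 targets (-0.47) and imprinted genes (-0.33).

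The construct lines were placed on a scale from 0 at the empty vector line to 1 at EBRTcH3, over the 1316 genes at least 2-fold apart between these 2 without LIF. The median position was 0.857 in MBD3a, 0.754 in MBD3b, between these 2 in MBD3c, and 0.552 in MBD-deleted, against 0.1 in coiled-coil-deleted and 0.042 in doubly deleted. The class means were 0.748 ± 0.138 and 0.071 ± 0.041 (SD, n = 4 and 2 lines; exact permutation p = 0.133, the smallest that 15 splits can give). Genes at least 2-fold away from the empty vector line without LIF numbered 1143 in MBD3a, 926 in MBD3b, 1197 in MBD3c and 804 in MBD-deleted, against 86 in coiled-coil-deleted and 82 in doubly deleted. All of these share the 1 empty vector array: in simulated lines with no difference, noise alone carried 77 genes past 2-fold and gave positions of 0.37 to 0.5. Against the empty vector array with LIF, the counts with LIF were 203 in coiled-coil-deleted, 286 in doubly deleted and 540 to 701 in the retaining lines.

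EBRTcH3 stood apart from the 7 lines made from it on chromosomes 8, 14 and 15 and in Y-linked genes, with the largest gaps in Uty and Eif2s3y. Uty stood at 9.27 and Eif2s3y at 9.48 log2 in EBRTcH3 with LIF (8.24 and 8.78 without), against 3.61 to 5.7 and 5.42 to 6.71 in the other 7 lines, although all are labelled male. The 4 other Y-linked genes measured lay near the floor: with LIF Kdm5d stood at 3.51 in EBRTcH3 and 3.50 to 3.81 in the other lines, Zfy1 at 4.44 and 3.42 to 3.85, Zfy2 at 3.84 and 3.12 to 3.45, and Usp9y at 3.00 and 2.53 to 2.67. Without LIF Zfy1 stood at 4.87 in EBRTcH3 and 3.42 to 3.83 in the other lines. Zfy2 then stood at 3.58 and 3.11 to 3.47, Usp9y at 2.66 and 2.46 to 2.62, and Kdm5d at 3.55 and 3.53 to 3.74. The median of the genes on chromosome 8 in EBRTcH3 was -0.26 log2 against the other lines in both conditions, with 80% of 610 genes lower with LIF and 81.5% without. Chromosome 14, where the shift lay in part of the chromosome, had medians of -0.17 and -0.11 and chromosome 15 of 0.09 and 0.17, while the 17 other chromosomes lay between -0.07 and 0.04.

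**Figure D4:**
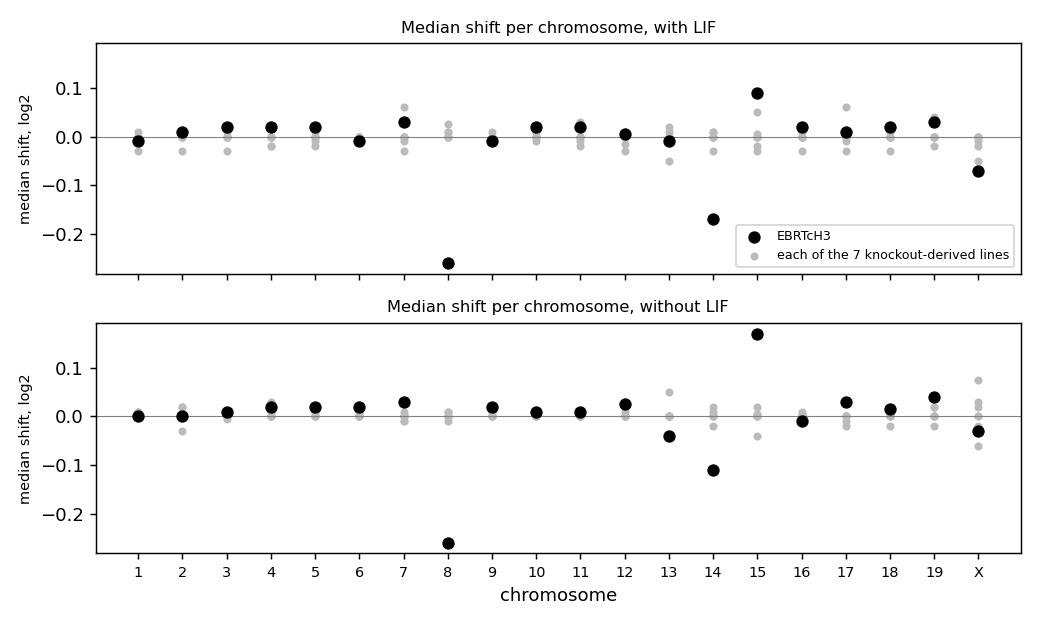
Median shift of the genes on each chromosome in each line, against the median of the 7 lines made from EBRTcH3. Black, EBRTcH3; grey, the other lines.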

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

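Of the tests in this part, those of the title runs, of a compressed signal range and of the absence of MBD3 as an explanation were chosen only after the results were seen. Lines far from the others of their class, in 5 of 25 sets of values tested where chance gives about 1 in 20, were MBD-deleted for the shift on the first principal component (57.8), the cell cycle list (0.055) and the feeder list (0.318). EBRTcH3 was such a line for the primed epiblast list (0.834) and the 2-cell-like list (-0.016). The list values are means of the response to LIF withdrawal in the retaining lines. The other results listed for a closer look are differences between the classes of line: 2760 genes with a different response, and lacking minus retaining differences of -0.217 in the SD of the response, 0.536 in the pluripotency list, -0.482 in the endoderm list and -0.868 in the mesenchyme list.

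For the class differences, 1 of the 56 splits of the 8 lines into 5 and 3, the real one, gave as many genes. The counts were 2760 in response against at most 2 in any other split, 3233 with LIF against 7, and 4791 without LIF against 0. A share of 1 in 56 is the smallest that these splits can give. The 3 comparisons use the same 8 lines and are not independent. The splits also cannot tell the coiled coil from other differences between these lines. For LIF withdrawal over all lines, 1 of 100 sign flips of the pairs gave as many genes (5715, highest other 4771, when the doubly deleted line alone was flipped). In the retaining lines 16 flips (8181, highest other 0) and in the lacking lines 4 flips (670, highest other 0) are too few for a share under 0.05.

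The smaller response of the 3 lacking lines was the first pattern weighed. Title runs as array batches are argued against as its source, since in both runs each retaining line had a larger SD of response than each lacking line, by 0.187 and 0.145 against an SD of 0.042 between lacking lines. They are not excluded, because in each run 1 of the classes is a single line. A compression of all signals alike is argued against too. The LIF and STAT3 target list fell on average 1.37 times as far in the lacking lines as in the retaining lines (1.28 to 1.508 with any 1 line left out), while the SD of all responses was 0.605 times as large. The list means of single lines overlapped, however (-0.85 to -0.71 in the lacking lines, -0.79 to -0.41 in the retaining lines). They also take in members that rose in the retaining lines, such as Ier3, so the ratio does not measure falls alone. Of the 4 largest falls of the list in the lacking lines, Socs3 (-1.87 against -1.27) and Bcl3 (-1.49 against -0.83) exceeded the retaining lines. Klf4 (-1.73 against -2.44) and Tbx3 (-1.26 against -1.95) fell less far than there. A compression of part of the genes is thus not excluded. For 1179 genes (869 risen and 310 fallen in the retaining lines), the share of the response difference lying in the levels without LIF was taken. Its median was 0.73 (0.664 to 0.772 with any 1 line left out). Levels already shifted with LIF thus account for the smaller part at the median. That median pools rises and falls and need not hold for single genes. Abca1 and Nr0b1, which fell in the retaining lines, were already lower with LIF in the lacking lines. A candidate explanation is that exit from the naive state may need the coiled coil of MBD3 while the fall of part of the LIF and STAT3 targets does not. This hypothesis was found on the same data, rests on 3 lacking lines and has no test of its own here. MBD-deleted, which retains the coiled coil, goes against it in part. Its pluripotency response was -0.46, against -0.44 in doubly deleted. Without LIF its pluripotency mean was 10.03, within the 10.01 to 10.14 of the lacking lines. Its primed epiblast response (1.2) went the other way, above the 0.3 to 0.49 of the lacking lines. MBD3 protein was not analysed here.

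EBRTcH3, apart from its 7 derivatives on chromosomes Y, 8 and 14, was the second pattern. Adding MBD3 back did not return chromosome 8 toward EBRTcH3. The chromosome 8 median of MBD3a lay 0.26 above that of EBRTcH3 with LIF, and those of the other derivatives lay above it too. This argues against levels that follow the present MBD3. It cannot exclude a lasting change that arose when MBD3 was removed, a step that all 7 lines share. A difference in chromosome 8 copy number could give the shift of that chromosome: all 4 blocks of genes along the chromosome were lower in EBRTcH3 in both conditions, the highest at -0.16, and a gain of chromosome 8 is a known culture change of mouse ESCs. For chromosome 14 the shift lay in the last 2 of 4 blocks (-0.43 and -0.20 with LIF). DNA copy number was not analysed here, and loss of Y in the founder of the 7 lines is untested.

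With LIF, the MBD-deleted and doubly deleted lines lay together on the third principal component, at -29.1 and -27.6, which was the third pattern. An array batch shared by the whole title run would shift its other arrays too, but the 4 others lay at least 27.1 away. The 14 other arrays spread from -6.7 to 13.8. The pattern was itself picked on this component, so these distances are part of its description and not a separate test. A batch of the arrays with LIF of that run stays open, since only 1 of the 4, coiled-coil-deleted, was with LIF. Deletion of the MBD stays open too as a possible explanation. The 2 differences that the deletion makes, which share no array, correlated across genes at 0.347 with LIF and 0.132 without. Before the result was seen, 0.2 in both had been set as the need and under 0.1 as the bound against it.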

How the results depend on the processing

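The fits without chromosomes 8, 14, 15 and Y and with 3 retaining lines at a time were chosen only after the results were seen. Over the alternatives, of 11048 values for the 628 calls of genes that the rule takes or the text names, 9910 stayed past the threshold and 1134 did not, 468 of these within the second run of titles. In that run, where the retaining class holds 1 line, 4 changed sign in the retaining lines: Ankrd37 (-0.13), Hoxd10 (-0.11), Msx1 (-0.02) and Tek (0.42). The comparisons kept their counts within 1.5 times in 225 of their alternatives; the others follow, and for those the cause was not tested unless given. A minimum of 2-fold leaves, by construction, 550, 1179 and 151 genes for LIF withdrawal in all, retaining and lacking lines, 886 for the difference in response, 502 and 754 for the class difference with and without LIF, and 671 and 563 for the coiled-coil deletion without and with LIF. Within the second run, with 3 lines and fewer arrays, limma called 18 genes over all lines and 0 for each other comparison of LIF or class; within the first run, where the lacking class is the empty vector line alone, it called 84 in the lacking lines, 732 for the response, and 680 and 1822 for the classes with and without LIF. Array weights gave 1611, 5414 and 5373 genes for the lacking lines, the response and the class with LIF, and the run of titles as covariate 1117 for the lacking lines. Robust and trended moderation gave 407 genes for the MBD deletion with LIF. With any 1 line left out the counts were 3645 (without MBD3c; 3761 without MBD3a) to 6831 (without doubly deleted) over all lines, 114 (without the empty vector line; 266 without coiled-coil-deleted, 280 without doubly deleted) to 1039 (without MBD-deleted) in the lacking lines, and 1353 (without coiled-coil-deleted; 1369 without doubly deleted) to 3914 (without MBD-deleted) for the response. They were 1779 (without coiled-coil-deleted; 1852 without doubly deleted) to 3866 (without MBD-deleted) with LIF and 3014 (without doubly deleted) to 5433 (without MBD-deleted) without LIF. Where the lacking class then holds 2 lines, the fit pools the spread over lines. With 3 retaining lines the lowest count there was 4681, from fewer arrays. Without the block by line, LIF withdrawal gave 5190, 8259 and 693 genes in all, retaining and lacking lines, so the pairing changed no call by over 1.5 times; no paired analysis of the class comparisons was possible because a line belongs to 1 class, and with all 16 arrays and the line as a random block they gave 4471 and 4314 genes.

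Median centring moved the pluripotency difference per line from 0.536 to 0.484 (exact permutation p = 0.0714) and raised the share of genes called higher from 60.4% to 70.8% over all lines and from 59.5% to 70.2% in the retaining lines, and lowered it from 34.5% to 23.6% for the response and from 40.8% to 28.7% for the class without LIF, with the median of all genes moving by at most 0.062. A limit of 1.5-fold against the empty vector line counts, by construction, more genes with LIF (EBRTcH3 2426, MBD3a 2171, MBD3b 2662, MBD3c 1982, MBD-deleted 2877, coiled-coil-deleted 1385, doubly deleted 1958) and without (3526, 3188, 2705, 3258, 2322, 564 and 504). Without LIF the filter at the 60th percentile, with fewer genes, left 52 in coiled-coil-deleted and 38 in doubly deleted, and no filter gave 128 in doubly deleted. Of the camera calls 0 of 73 held with an estimated correlation; over all alternatives 137 list calls were lost and 53 gained, with no called list changing direction. List medians changed sign with a scaling in 10 cases, none of a called list and none over 0.07. A gene with no call was counted as reversed only if a call was made under the alternative, a rule set after small values of Mbd3 near 0 had changed sign. Signal over background limits the genes near the floor: without the filter 7926 genes passed in the retaining lines, and 533 in the lacking lines.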

Other observations

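The overlap counts and the neighbours of Peg3 were chosen only after the values were seen, unlike the limma comparisons, and the genes were grouped here for the direction of their change. Some genes responded more to LIF withdrawal where the coiled coil was lacking. Slc38a5, a glutamine transporter gene, responded by 0.48 ± 0.23 (SD, n = 5 lines) in the retaining lines and by -1.97 ± 0.52 (SD, n = 3 lines) in the lacking lines (difference -2.45 ± 0.22, SE, adjusted p = 0.000123), from a level with LIF that was 3.45 higher in the lacking lines. The protease inhibitor gene A2m (0.09 and -1.80, adjusted p = 0.000203) and the prohormone-processing gene Cpe (0.08 and -1.72, adjusted p = 0.000369) fell in the lacking lines and did not pass in the retaining lines. In the retaining lines A2m stood at 4.40 with LIF and 4.49 without, and Slc38a5 at 4.84 with LIF. The array medians were 4.72 to 4.85, so these 2 genes had little room to fall there. Cpe stood at 6.70 with LIF in the retaining lines. Sfmbt2, a polycomb-group gene active in trophoblast, rose by 0.49 and 1.88 (difference 1.39 ± 0.17, adjusted p = 0.000741), Id2 by 1.15 and 2.44 (adjusted p = 0.00244) and the X-linked Rhox5 by 1.80 in the lacking lines (0.53 in the others, adjusted p = 0.0337). The Rhox5 call was lost without MBD3a (1.28), MBD3c (1.17), the empty vector line (0.99), coiled-coil-deleted (1.46) or doubly deleted (1.35), and its rise in the lacking lines without the empty vector line (1.52). With LIF, Sfmbt2, Id2 and Rhox5 were lower in the lacking lines (-1.87, -1.83 and -1.33). Without LIF the class difference did not pass with all lines (-0.47, -0.54 and -0.07; adjusted p = 0.0703, 0.121 and 0.934), but did for Sfmbt2 without EBRTcH3 (-0.33, adjusted p = 0.0125) and for Id2 without MBD-deleted (-0.67, adjusted p = 0.035). Elf5 was different: with LIF its levels differed by 0.04 (adjusted p = 0.873) and without LIF it was higher in the lacking lines by 1.11 (adjusted p = 0.000137).

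A run of 4 neighbouring genes of the imprinted Peg3 domain on chromosome 7 moved together. In the retaining lines LIF withdrawal raised Zim1 by 1.84 ± 0.19 log2 (SE, n = 5 lines), Peg3 by 1.79 ± 0.17, its antisense gene Peg3os by 1.97 ± 0.18 and Usp29 by 1.72 ± 0.27. Without LIF all 4 were lower in the lacking lines (-2.09 ± 0.35, -2.23 ± 0.34, -2.06 ± 0.32 and -2.28 ± 0.40), and with LIF they were lower too (-0.56, -1.37, -0.84 and -1.31). The nearest measured genes on either side, Zim2 (0.07, adjusted p = 0.613) and Aurkc (0.21, adjusted p = 0.0741), did not pass without LIF. Of the 4, the difference in response itself passed for Zim1 (-1.53 ± 0.31, adjusted p = 0.00979) and Peg3os (-1.22 ± 0.29, adjusted p = 0.0197) and not for Peg3 (adjusted p = 0.0707) or Usp29 (adjusted p = 0.189). Peg3 did pass there without MBD-deleted (adjusted p = 0.0267) or doubly deleted (-1.15, adjusted p = 0.0433). Peg3os did not without the empty vector line (-1.14, adjusted p = 0.062) or coiled-coil-deleted (-1.11, adjusted p = 0.0903), nor with LIF without doubly deleted (-0.66, adjusted p = 0.0534).

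Genes called in both classes of line upon LIF withdrawal mostly moved the same way: 257 rose in both (83.3 by chance) and 175 fell in both (40.4 by chance), against 31 and 16 that went opposite ways (59.4 and 56.6 by chance). Between the class differences with and without LIF, 566 genes were higher in the lacking lines in both (149.6 by chance) and 604 lower in both (183.9 by chance), against 172 higher with LIF and lower without (217 by chance) and 68 the reverse (126.8 by chance). Both class differences use the same lines in the same classes, so lasting differences between lines recur in both. The counts by chance assume independent comparisons, so this overlap is in part built in.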
